A study of Homo sapiens with 4 samples.

How the data were processed

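Cells labelled SKOV3, a human line from an ovarian carcinoma, were grown in McCoy's 5A medium with serum and given fresh medium with 0.5 μM elaiophylin and sampled at 0, 3, 6 and 12 h. Total RNA taken up in TRIzol was labelled with Cy3 and hybridized, 1 sample per array, to the NimbleGen Human 12×135K expression array. Each row of the deposited table holds 1 transcript target, and its deposited values were intensities on a linear scale, all positive and up to 50365. Scanning, background correction, summarisation of probes and normalization are not given in the sources used here. The deposited intensity distributions were nearly the same on the 4 arrays: the 5th percentile lay between 11.9 and 12.1 and the 95th between 11812 and 11957. The arrays had therefore been brought to a common distribution before deposition, which would remove any shift shared by most genes, and no change in total RNA per cell can be read from them.

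Intensities were converted to log2 values with no offset and no further normalization. Of 45033 rows, 18188 were named from the platform's gene table, of an older annotation, and 678 by their transcript accession in the RefSeq gene table of GRCh38.p14. The other 26167 rows had no gene name and entered no gene count, and no row named several genes. Rows of 1 gene symbol were averaged on the log2 scale, which gave 17185 genes. Background was set at the 95th percentile of 361 olfactory receptor genes over the 4 arrays, an intensity of 33.3 (log2 5.06). A gene was counted when its highest value of the 4 arrays reached that level, which held for 13324 genes. Where a gene lay below background on an array, its fold was taken against the background level and written as "at least", while counts, log2 changes and list medians used the values as measured unless another floor is named.

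The labels give 1 array per time and no replicate number, so no comparison of 2 arrays had a test. Genes with a log2 difference of at least 1 in size, a 2-fold difference, were counted at 3, 6 and 12 h against 0 h and between consecutive times. How far values move without any change of expression was described by the olfactory receptor genes and by 100 simulations of 4 unchanged arrays, which share a 0 h array as the real ones do. The spread between rows of 1 gene was also taken. It compares targets on the same 2 arrays and leaves out variation between RNA samples or cultures. The noise by level in these simulations was taken from the step from 3 h to 6 h. That step may hold real changes with time, which would set the noise too high. It also joins the most alike pair of arrays, and noise particular to the 0 h array is not covered. The simulated test data described below used the same noise. The secondary model was a straight line over hours for each gene, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg threshold 0.05). It had 2 residual degrees of freedom, and its residual is the departure from a line in time, not an error between replicates. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

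For 33 gene lists the median log2 change of the members over background was set against 10000 random lists of the same size, matched on mean level in 20 bins. A median at or above the 97.5th percentile of those is called high, and one at or below the 2.5th is called low. These percentiles describe where a list stands among the genes of the same arrays and are not p-values over replicates. The lists covered the responses of the ER (chaperones, ATF4 and CHOP targets, aminoacyl-tRNA synthetases, COPII and Golgi transport), heat shock, ERK output, immediate early genes, MAPK components, autophagy, lysosomes, cholesterol and fatty acid synthesis, NRF2 targets, metallothioneins, p53 targets, apoptosis regulators that promote or oppose death, G1/S and G2/M genes, NF-kB and interferon targets, hypoxia and glycolysis, ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, proteasome, calcium handling, YAP/TAZ and TGF-beta targets, epithelial and ovarian carcinoma markers, fibroblast, leukocyte and endothelial markers, and reference genes. Lists with fewer than 5 members over background, the leukocyte and endothelial markers, were given gene by gene. Genes named in the text were the 10 with the largest rise and the 10 with the largest fall at each time against 0 h, the up to 4 members of each list with the largest absolute change at each time, and 12 genes fixed whatever their values: DDIT3, HSPA5, ATF4, XBP1, SQSTM1, MAP1LC3B, DUSP6, EGR1, FOS, SOS1, PTPN11 and EGFR. Clone and locus numbers were not named. The value of 1 gene that the rule takes is not reported here. Lists, thresholds, the rule for named genes and the main alternative settings were fixed before the data were examined. The stratified squamous and the epithelial adhesion lists, the genes around ERBB2 and CDKN2A, and the gene families of the last part were chosen after the values had been seen, and so were all genes named only from them.

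Alternative settings were quantile normalization, arrays centred on their medians, cyclic loess, no filter on dim genes, filters at the median and at the 75th percentile of all values, the row with the highest mean level for each gene, 50 intensity units added before the log2, thresholds of 1.5-fold and 3-fold, random lists not matched on level, the mean in place of the median, time as log2(hours + 1), and the 3 treated arrays against the 0 h array. Alternatives chosen after seeing the data were the 3 h array as reference in place of the 0 h array, counts without the squamous and epithelial lists, a filter asking that the brighter of the 2 arrays compared lie 2 log2 units above background, and values below background set to the background level. The steps were tested on simulated data for the 12 h comparison with 50 genes for each size of change. A difference of at least 2-fold in the right direction was found for 44% of genes with a log2 change of 1 and for 100% of those with a log2 change of 2, 3 or 4. The line over hours was called for 2%, 90%, 100% and 100% of them. The simulated changes were themselves straight lines in hours, so these shares do not carry over to genes with another time course. Of 13124 unchanged genes 0.731% were 2-fold apart and 1 was called by the line, and 5.5% of 200 lists of unchanged genes were called high or low. Noise was drawn for each gene separately, so that share does not cover lists whose genes move together. A list of 25 changed genes stood at percentile 100. Positions of genes are from the RefSeq gene table, and the positions of the array's probes within the transcripts were not analysed here.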

Results

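Gene expression was measured in cells labelled SKOV3, a human ovarian carcinoma line, at 0, 3, 6 and 12 h in medium with 0.5 μM elaiophylin, a macrodiolide antibiotic made by Streptomyces. The compound is described in the literature as acting on autophagy, on stress of the endoplasmic reticulum (ER) and on MAPK signalling, and the comparisons ask how transcript levels differed with the time of exposure. Each time had 1 one-colour array, with 0 h as the study's control, so there were 4 arrays and no replicates. Their number limits the precision, and each value is a single measurement with no replicate error. Median intensity over all 45033 targets was 313 at 0 h and at 3 h, 316 at 6 h and 312 at 12 h, and 73.0% to 74.0% of named genes lay at or over background on each array. Across genes over background, log2 levels at 0 h correlated with those at 3, 6 and 12 h with r = 0.978, 0.976 and 0.964. Between treated arrays r was 0.994 for 3 and 6 h, 0.989 for 6 and 12 h and 0.983 for 3 and 12 h. Olfactory receptor genes, taken as not expressed, had an SD of log2 change of 0.44, 0.43 and 0.40 at 3, 6 and 12 h, and 3.05%, 2.22% and 2.49% of them were at least 2-fold apart. Where 1 gene had several targets, the median SD between their changes was 0.107, 0.0868 and 0.111, which leaves out variation between RNA samples or cultures. "Higher" and "lower" stand for measured differences between 2 arrays, since no comparison of single arrays can be tested, and the design has no array with fresh medium alone.

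After 3 h, CHAC1, GEM, DDIT3, INHBE, PTGS2, ATF3, NR4A3 and NR4A1 were among the 10 genes farthest above 0 h. CHAC1, an enzyme that breaks down glutathione, was 12.2-fold higher, and DDIT3, which encodes the stress transcription factor CHOP, was 8.74-fold higher, from an intensity of 1955 to 17095. ATF3, a stress-induced transcription factor, was 7.04-fold higher, INHBE, a subunit of activin E, 7.27-fold and GEM, a small GTP-binding protein, 10.3-fold. EGR3 and EGR4, growth-responsive transcription factors, lay below background at 0 h and were at least 7.62-fold and 6.14-fold higher, so their rank cannot be read. The nuclear receptors NR4A1 and NR4A3 had log2 changes of 2.54 and 2.73, and PTGS2, the inducible cyclooxygenase, of 2.86. In all, 240 of 13324 genes were at least 2-fold higher (1.80%) and 380 at least 2-fold lower (2.85%). Simulated unchanged arrays, with noise taken from the step from 3 h to 6 h, gave means of 57.5 and 57.3. With values below background set to background, a choice made after the data were seen, the numbers were 216 and 301, and 322 and 377 at 6 h and 643 and 761 at 12 h. Of the 3331 genes with the lowest mean level 310 were lower, and of the 3331 with the highest 1 was. That mean is over all arrays, so a fall after 0 h itself lowers it, and this contrast is partly built in. Of 31 list medians 12 were high and 3 low, where lists of independently drawn genes would give 0.775 each. Genes of a real list may move together and some lists share members, so that number is no measure of chance for them.

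Several genes far below their 0 h level had treated values below background, so which differences downward were largest cannot be read. S100A8 and S100A9, calcium-binding proteins of squamous cells and myeloid cells, were at least 40.0-fold and 98.3-fold lower at each of the 3 times, with treated levels below background. COL17A1, a hemidesmosome collagen of basal keratinocytes, was at least 44.2-fold lower, RAB25, a GTPase of epithelial membrane traffic, at least 57.6-fold, SERPINA3, a protease inhibitor, at least 45.5-fold and IRX2, a homeobox factor, at least 58.7-fold. FXYD3, a regulator of the sodium pump, had log2 changes of −5.61, −5.73 and −6.39. KRT6A went from an intensity of 5220 at 0 h to 90.5, 104 and 77.3, and the keratins KRT6B and KRT6C had log2 changes of −6.29 and −6.26 at 3 h, although these 3 genes are nearly identical in sequence and which of them was measured is uncertain. A pair of lists chosen after these values were seen covered such genes. Among 42 markers of stratified squamous epithelium the median log2 change was −2.35, −2.76 and −2.72 at 3, 6 and 12 h (percentile 0 each), with 28, 29 and 31 members at least 2-fold lower (25, 26 and 28 with values below background set to background) and 0 higher. Among 27 genes of epithelial adhesion and identity it was −2.28, −2.24 and −2.73 (percentile 0 each), with 20, 22 and 19 members lower (19, 21 and 19 on that floor) and 0 higher. On the same floor the squamous medians were −1.97, −2.43 and −2.67 and the epithelial ones −2.28, −2.15 and −2.44. From 3 h to 12 h the medians were 0.00, which changed sign with quantile normalization, and −0.07, but 19 of the 46 members lower at all 3 times lay below background on each treated array, where no further difference can be read. Of the members at least 2-fold lower at 12 h, 20 were still measurable at 3 h, and their median from 3 h to 12 h was −0.28, with quartiles of −0.48 and −0.15. KRT14 and KRT17, keratins of basal and stressed keratinocytes, did not share the difference, with intensities of 11542 and 35574 at 0 h and of 10984 and 38357 at 3 h. Without these lists 332, 418 and 810 genes were lower at 3, 6 and 12 h, and the counts of higher genes were 240, 362 and 700 as before.

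**Figure D1:**
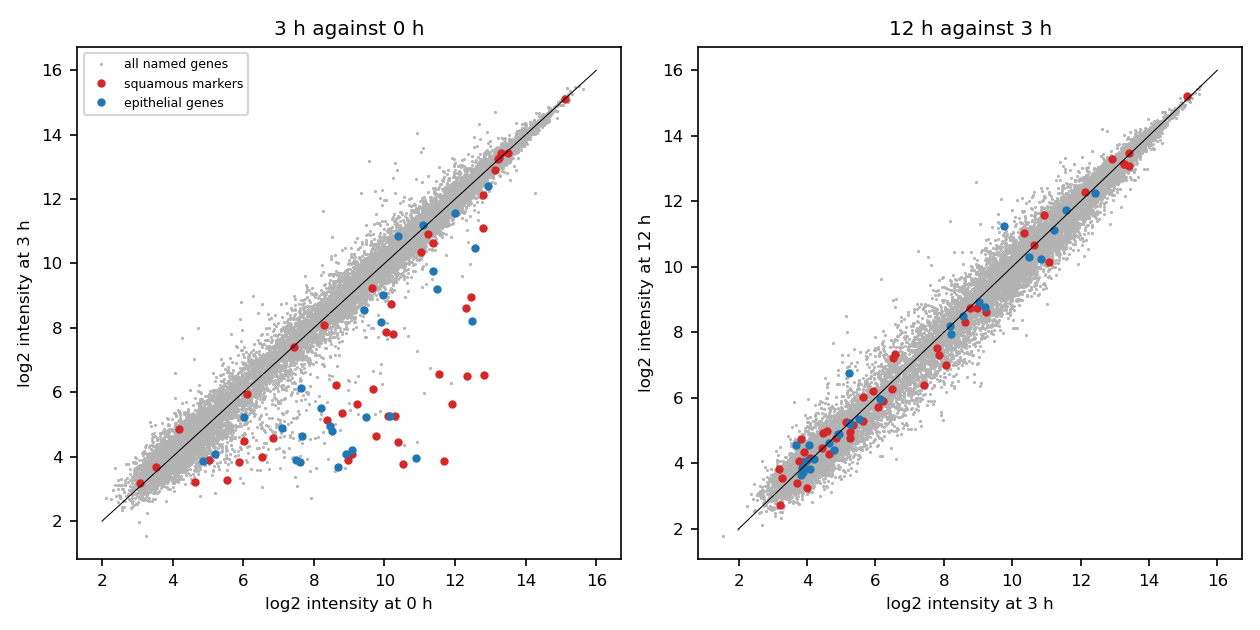
Log2 intensity of each gene at 3 h against 0 h (left) and at 12 h against 3 h (right), with squamous genes in red and epithelial genes in blue. At 3 h against 0 h, 28 of 42 squamous and 20 of 27 epithelial genes lie at least 2-fold under the diagonal and 14 and 7 within 2-fold of it, and at 12 h against 3 h 40 and 25 lie within 2-fold.

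After 6 h, CHAC1, DDIT3, GEM and INHBE were again among the 10 genes farthest above 0 h. INHBE was 14.8-fold higher than at 0 h, DDIT3 9.66-fold and CHAC1 9.37-fold. FGF21, a hormone of metabolic stress, had a log2 change of 3.32, PPP1R15A, the GADD34 subunit that brings a phosphatase to eIF2α, of 2.87 and SESN2, a stress-induced inhibitor of mTORC1, of 2.58. GEM was 10.2-fold higher. The cytokines IL20 and CXCL8 had log2 changes of 2.84 and 2.54, and PTX3, a pentraxin of innate immunity, of 2.65. At this time 362 genes were at least 2-fold higher (2.72%) and 469 lower (3.52%), with the squamous list's median at −2.76. With the 3 h array in place of the 0 h array, a choice made after the data were seen, 62 were higher and 122 lower. Among the list medians 13 were high and 4 low.

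After 12 h, the largest difference upward among genes over background at 0 h was that of CSF2, and GEM, PTX3 and INHBE were among the 10 largest as at 6 h. CSF2, which encodes the cytokine GM-CSF, was 24.0-fold higher than at 0 h, GEM 18.7-fold, FGF18, a fibroblast growth factor, 15.0-fold and PTX3 3.89 on the log2 scale. CREBRF, a regulator of the ER stress factor CREB3, was 13.6-fold higher, INHBE 12.6-fold, and RBM15, an RNA-binding protein, MAFF, a small Maf transcription factor, and TCP11L2 had log2 changes of 3.53, 3.31 and 3.25. SPINK1, a trypsin inhibitor, lay below background at 0 h and was at least 10.98-fold higher, so its rank cannot be read. CSF2 and FGF18 were late: their log2 changes were 0.93 and 0.45 at 3 h, and 4.59 and 3.91 at 12 h. In all, 700 genes were at least 2-fold higher (5.25%) and 860 lower (6.45%), with the squamous list's median at −2.72. Against the 3 h array, again a choice made after the data were seen, the counts were 343 and 476. Among the list medians 11 were high and 1 low.

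Many genes recurred from time to time. At all 3 times 131 genes were at least 2-fold higher and 283 lower, where independent counts would give 0.343 and 0.863 and unchanged arrays that share the 0 h array 3.74 and 3.34. Part of this excess may come from the shared 0 h array, since an error in it enters each comparison. Of the 700 genes higher at 12 h, 140 were so at 3 h, 263 at 6 h and 428 at neither. Of the 860 lower ones the numbers were 305, 363 and 475. The consecutive steps that leave out the 0 h array were smaller. From 3 h to 6 h 62 genes were at least 2-fold higher (0.465%) and 122 lower (0.916%), and from 6 h to 12 h 182 (1.37%) and 185 (1.39%). Of the olfactory receptor genes, mostly below background, 4.43% and 1.66% were at least 2-fold apart in these steps. From 3 h to 12 h, which also leaves out the 0 h array, 343 were higher and 476 lower. These are more than the 240 and 380 at 3 h against 0 h and fewer than the 700 and 860 at 12 h. Of 31 list medians 8 were high from 3 h to 6 h (ER chaperones, ATF4 and CHOP targets, tRNA synthetases, ERK output, cholesterol, NF-kB, calcium handling, COPII and Golgi) and 6 low (heat shock, metallothioneins, G2/M, ribosomal proteins, ribosome biogenesis, oxidative phosphorylation). From 6 h to 12 h 9 were high (ER chaperones, heat shock, ERK output, immediate early, lysosomal, metallothioneins, p53 targets, death-promoting regulators, NF-kB) and 2 low (cholesterol, G1/S). A straight line over hours called 0 rising and 0 falling genes of 13324 after Benjamini-Hochberg adjustment in limma, with 1431 rising and 1649 falling at an unadjusted p under 0.05. With the filter at the median of all values it called 144 and 167.

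Genes of protein folding in the ER were higher as a group. The 32 ER chaperones and degradation factors had medians of 0.39, 0.58 and 0.57 at 3, 6 and 12 h (percentile 100 each), with 4, 11 and 12 members at least 2-fold higher (11 at 12 h with values below background set to background) and 0 lower. HSPA5, the ER chaperone BiP, was 3.29-fold, 4.23-fold and 4.58-fold higher, its co-chaperone DNAJB9 had log2 changes of 1.90, 2.11 and 2.34, and HERPUD1, a factor of ER-associated degradation, of 1.64, 1.74 and 1.67. XBP1, a transcription factor of the unfolded protein response, had 1.17, 1.10 and 1.08, and SYVN1, an ER ubiquitin ligase, 1.62 at 6 h. ERO1B, an ER oxidase, lay below background at 0 h and was at least 2.93-fold higher at 12 h. The 32 measured ATF4 and CHOP targets had medians of 0.34, 0.65 and 0.75 (percentile 100 each), with 9, 12 and 12 members higher and 0 lower. PPP1R15A had log2 changes of 2.42, 2.87 and 3.17, whereas ATF4 itself, whose control is known to lie largely in translation, had 0.26, 0.39 and 0.27. Both lists also stood at percentile 100 from 3 h to 12 h, with medians of 0.29 and 0.23. The 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs and include ATF4 targets, had smaller medians of 0.11, 0.25 and 0.32 that were high at each time, and no member reached 2-fold. Their highest values at 12 h were 0.76 for EPRS1 and 0.52 for CARS1, and the call at 3 h ended with unmatched random lists and with means. The 29 COPII and Golgi transport genes had medians of 0.14, 0.31 and 0.31, all high, although the call at 3 h ended under the same pair of settings. SEC24D, a cargo adaptor of COPII vesicles, had log2 changes of 0.79, 1.25 and 1.22, GORASP2, a Golgi stacking protein, of 0.62 and 0.72 at 3 and 6 h, and ARFGAP3 of 1.01 at 12 h.

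**Figure D2:**
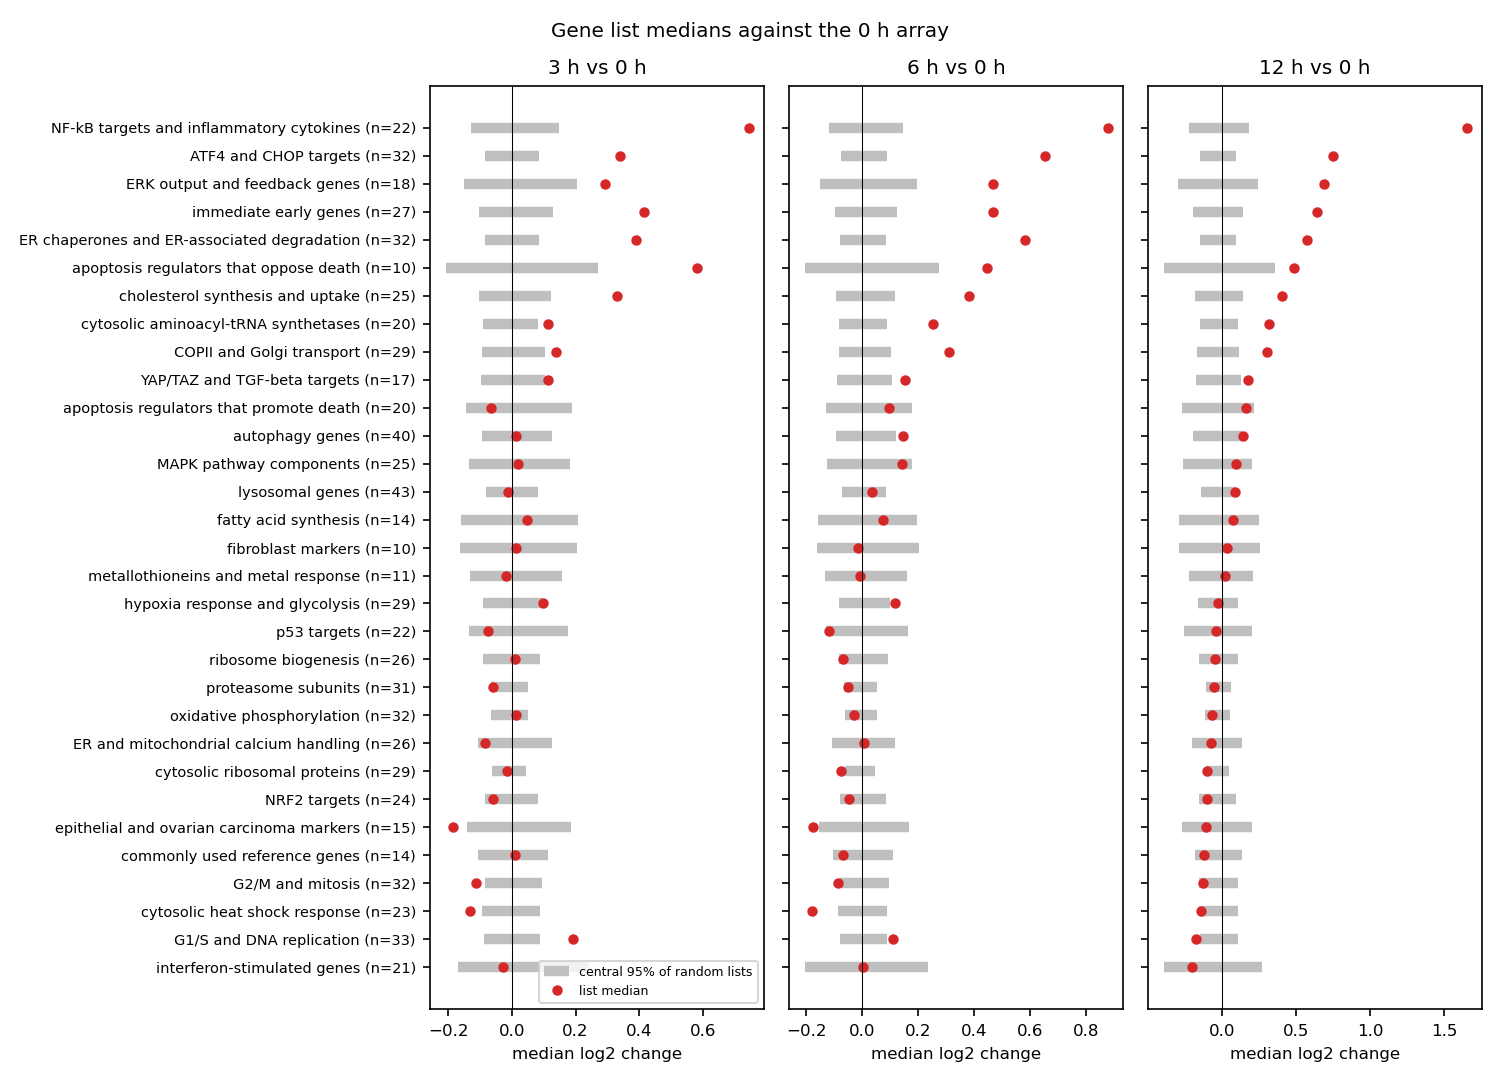
Median log2 change against 0 h of 31 gene lists at 3, 6 and 12 h (points), with grey bars for the central 95% of random lists of the same size and level. The NF-kB list reaches 1.65 at 12 h, the ATF4 and CHOP list 0.75, and the heat shock list lies at −0.13, −0.18 and −0.14.

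Cytokine genes and other NF-kB targets had the highest median of the 31 lists at each time. The 22 measured members had medians of 0.75, 0.88 and 1.65 (percentile 100 each), and 6, 10 and 17 of them were at least 2-fold higher with 0 lower. CXCL8, CXCL2 and CXCL3, chemokines that attract neutrophils, had log2 changes of 2.51, 1.90 and 2.16 at 3 h and of 3.10, 3.22 and 3.12 at 12 h. IL6, an inflammatory cytokine, had 1.56, 1.58 and 1.67, RELB, an NF-kB subunit, 1.94 at 6 h and BIRC3, an inhibitor of apoptosis that NF-kB induces, 2.26 at 12 h. From 3 h to 12 h the median was 0.75 (percentile 100) with 6 members higher. For interferon-stimulated genes the 21 members had medians of −0.03, 0.00 and −0.20, none of them called high or low, and a mean of −0.02 at 6 h. At 12 h IRF1 and IRF9, interferon-response transcription factors, stood at 1.69 and 1.39 while the antiviral gene OAS1 and the interferon-response regulator USP18 stood at −1.40 and −1.47.

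Immediate early genes and outputs of ERK signalling were higher, with members that went the other way. The 27 immediate early genes had medians of 0.42, 0.47 and 0.64 (percentile 100 each), with 7, 5 and 8 members at least 2-fold higher and 1, 0 and 0 lower, but from 3 h to 12 h the median of 0.06 was not high (percentile 92.5). NR4A1 and NR4A3 were highest at 3 h and had 1.34 and 1.19 at 12 h, KLF4, a zinc-finger factor, had 1.92, 2.03 and 2.43, and ZFP36, which destabilizes AU-rich mRNAs, −0.82, 0.82 and 2.39. EGR1 and FOS, classic early response genes, lay below their 0 h level at each time, with −0.37, −0.59 and −0.73 and with −0.35, −0.22 and −0.47. The 18 ERK output and feedback genes had medians of 0.29, 0.47 and 0.69 (percentiles 99.7, 100 and 100), with 1, 4 and 7 members higher and 1, 1 and 0 lower, and the call at 3 h ended with the filter at the 75th percentile. DUSP5, an ERK phosphatase, had 1.42, 1.93 and 2.80, SPRY4, a feedback inhibitor of receptor signalling, 2.49 at 12 h, and FOSL1, an AP-1 subunit, 1.60, while SPRY2, a relative of SPRY4, was 3.997-fold higher at 12 h. DUSP6, another ERK phosphatase, had −0.70, −0.30 and 0.59, and SPRY1 had −1.47 and −1.52 at 3 and 6 h. The 25 MAPK pathway components had medians of 0.02, 0.14 and 0.09, none high or low, with a mean of −0.02 at 3 h, and 1, 1 and 3 members were at least 2-fold lower. EGFR had −0.18, 0.02 and 0.44, the RAS exchange factor SOS1 0.34, 0.40 and 0.43, and the phosphatase PTPN11 0.25, 0.16 and 0.43. ERBB2 and ERBB3, receptors of the EGF family, had −1.17 and −1.71 at 12 h, the latter −0.58 when only its brightest target was used, and BRAF, a RAF kinase, had 0.89.

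**Figure D3:**
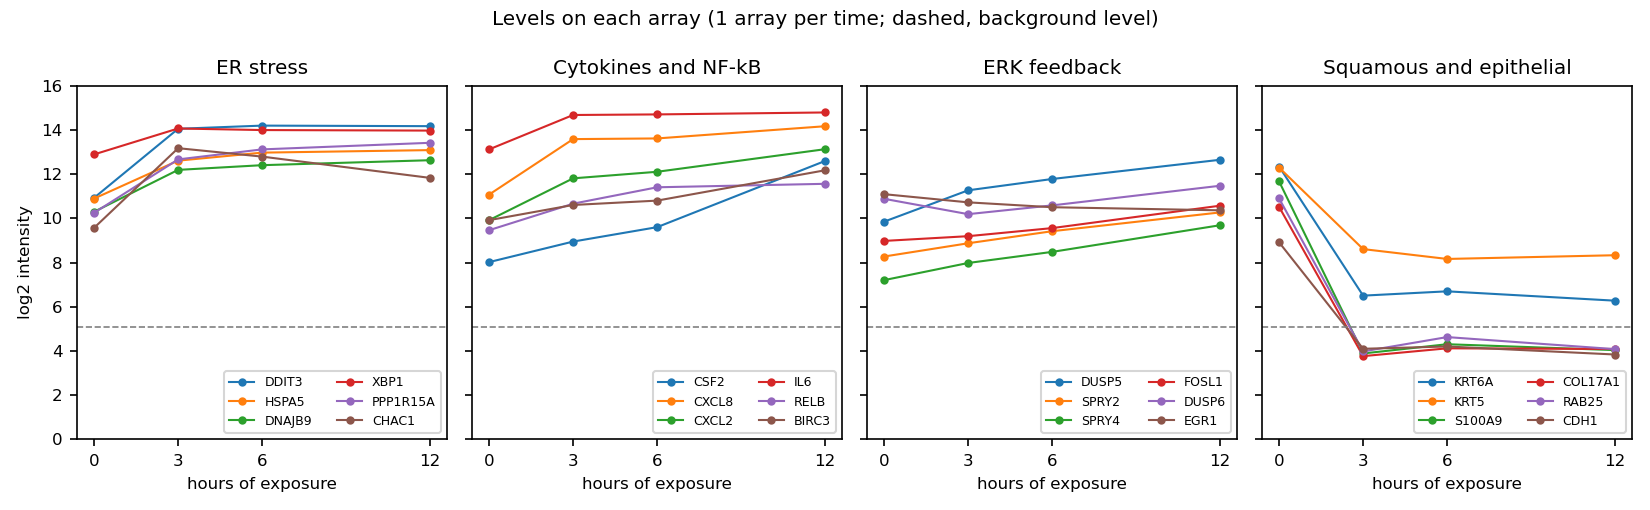
Log2 intensity against hours of exposure for genes of 4 groups (ER stress, cytokines and NF-kB, ERK feedback, squamous), 1 array per point, with the background level of 5.06 dashed. CSF2 lies 4.59 above its 0 h level at 12 h, DDIT3 between 3.13 and 3.27 above it from 3 h on, and S100A9 lies under background at 3, 6 and 12 h.

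Autophagy genes differed little. The 40 members had medians of 0.01, 0.15 and 0.14 (percentiles 48.7, 99.3 and 98.1), with 0, 1 and 2 at least 2-fold higher and 0 lower, and both high calls ended when means were used. The median from 3 h to 12 h was 0.08 (percentile 96.2), which was not high. WIPI1, which binds lipids of the forming autophagosome, had 0.61, 1.45 and 1.89, UVRAG, a partner of Beclin, 0.72, 0.81 and 1.01, and ULK1, the kinase that starts the process, −0.02, 0.75 and 0.87. SQSTM1, the cargo receptor p62, had −0.06, 0.41 and 0.77, and MAP1LC3B 0.14, 0.25 and 0.29. The 43 lysosomal genes had medians of −0.01, 0.03 and 0.09, none high or low, although the one at 12 h was high with quantile normalization, no filter, the filter at the 75th percentile and means, and the median from 3 h to 12 h was 0.13 (percentile 99.9). FNIP1 and FLCN, a complex that acts on Rag GTPases, had 1.94 and 1.91 at 12 h, RRAGC, one of those GTPases, 1.12, and the protease CTSH −1.60, while RRAGD had −1.46 and −1.17 at 3 and 6 h. The 25 cholesterol synthesis and uptake genes had medians of 0.33, 0.38 and 0.40 (percentile 100 each), with 2 members higher at each time, but −0.04 from 3 h to 12 h. STARD4, a sterol carrier, was 3.06-fold, 3.80-fold and 2.82-fold higher, INSIG1, which retains the sterol sensor in the ER, had log2 changes of 1.11, 1.13 and 1.26, and HMGCS1, an early enzyme of the pathway, of 0.96 at 3 h. The 14 fatty acid synthesis genes had medians of 0.05, 0.08 and 0.07 and a mean of −0.04 at 12 h, none high or low. ELOVL6, an elongase, had −1.05 at 6 h and GPAM, an acyltransferase, −1.21 at 12 h.

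The cytosolic heat shock list went the other way from the ER chaperones. The 23 members had medians of −0.13, −0.18 and −0.14 (percentiles 0.16, 0 and 4.0), low at 3 and 6 h, with 3, 3 and 2 members at least 2-fold lower and 0 higher, and the call at 3 h ended with unmatched random lists while the list was low at 12 h with means. From 3 h to 12 h the median was 0.03 (percentile 85.2), neither high nor low, and from 6 h to 12 h it was 0.12, which was high (percentile 99.9). HSPA1A, the inducible chaperone HSP70, went from an intensity of 19508 to 4660, 5566 and 7868, its relative HSPA1L had −1.25, −1.52 and −1.81, and HSPB8, a small heat shock protein, had 0.84 at 12 h. The 31 proteasome subunits had medians of −0.06, −0.05 and −0.05, none high or low, with PSMD12 at −0.62 at 12 h. The 24 NRF2 targets, genes of the defence against oxidants, had medians of −0.06, −0.05 and −0.10 and means of 0.03 and 0.01 at 6 and 12 h, none high or low. NFE2L2, which encodes NRF2, had 0.80, 0.76 and 0.93, and GCLC, an enzyme of glutathione synthesis, 1.04 at 12 h. The 11 metallothionein and metal response genes had medians of −0.02, −0.01 and 0.02 with a mean of 0.14 at 3 h, none high or low, while SLC30A1, a zinc exporter, had 0.89, 0.70 and 1.36. The 26 calcium handling genes had medians of −0.08, 0.01 and −0.08 with a mean of −0.00 at 6 h, none high or low. Calmodulin gene CALM3 had −1.03, −0.85 and −1.55, and the channel subunit ORAI3 −1.02 at 12 h.

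Apoptosis regulators of both kinds had members that stood higher. The 10 that oppose death had medians of 0.58, 0.45 and 0.48 (percentiles 100, 99.8 and 99.3), with 3 members at least 2-fold higher at 12 h, but from 3 h to 12 h the median of 0.21 was not high (percentile 95.7). BCL2, an inhibitor of mitochondrial apoptosis, had 0.69, 0.90 and 1.26, its relative BCL2L2 0.77, 0.81 and 1.02, and MCL1 0.74 at 3 h. The 20 that promote death had medians of −0.07, 0.10 and 0.16, none high or low, with 1, 2 and 3 members higher and 2, 1 and 2 lower. The median at 12 h was high with the filters at the median and at the 75th percentile of all values, and so was the one from 3 h to 12 h (0.14, percentile 97.6). PMAIP1 and BBC3, which encode the BH3-only proteins NOXA and PUMA, had 1.53 and 1.76 at 12 h, HRK, another of this family, 1.99 and BMF −1.17. The 22 p53 targets had medians of −0.07, −0.12 and −0.04, none high or low, and a mean of 0.19 at 12 h. Call and direction depended on the setting: the median at 6 h was low with quantile normalization and cyclic loess, and with the filter at the 75th percentile the medians were above 0 at all 3 times and high at 6 and 12 h (0.45 and 0.91). SESN2 stood at 2.44 at 12 h and PLK3, a stress kinase, at 1.87, while SESN1 had −1.10 at 3 h and SPATA18, of mitochondrial quality control, was at least 1.91-fold lower with all treated values below background.

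Cell cycle genes differed by small amounts. The 33 genes of G1/S and DNA replication had medians of 0.19 and 0.11 at 3 and 6 h, both high, and −0.17 at 12 h, which was low, with no member 2-fold apart. The calls at 6 and 12 h ended with unmatched random lists, and the one at 6 h also with means. From 3 h to 12 h the median was −0.29 (percentile 0). CDC6 and POLA1, which load helicases and prime DNA synthesis, had 0.63 and 0.56 at 3 h, and GINS1 and MCM10, parts of the replication fork, −0.94 and −0.92 at 12 h. The 32 genes of G2/M and mitosis had medians of −0.11, −0.09 and −0.13, low at 3 and 6 h, and these calls ended with the filter at the 75th percentile and with unmatched random lists. Between 3 h and 12 h the median was −0.03 (percentile 44.2), with no call. MKI67, a proliferation marker, had −0.46, −0.67 and −1.09, and PLK1, a mitotic kinase, −0.79 at 3 h.

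Of the remaining lists, the 29 hypoxia and glycolysis genes had medians of 0.10, 0.12 and −0.02 and a mean of 0.16 at 12 h, high at 3 and 6 h, and both calls ended with unmatched random lists, the first also with cyclic loess and with the 50-unit offset. Their 3 h to 12 h median was −0.03 (percentile 42.7), with no call. SLC2A3, a glucose transporter, had 0.83, 1.49 and 2.64, ADM, the vasodilator adrenomedullin, 1.64 at 12 h and VEGFA 1.04, while EGLN3, an oxygen sensor, had −1.59. The 17 YAP/TAZ and TGF-beta targets had medians of 0.11, 0.15 and 0.18, all high, and all 3 calls ended with the filter at the 75th percentile and with unmatched random lists, the first also with quantile normalization. Their median of 0.06 from 3 h to 12 h was not high (percentile 91.8). ANKRD1, a YAP target, had 0.97, 1.31 and 1.95 and SKIL, a repressor of SMADs, 0.79, 0.86 and 1.43. The 29 ribosomal protein genes had medians of −0.02, −0.07 and −0.10, low at 6 h except with unmatched random lists and at 12 h with means or the filter at the 75th percentile alone, with no member 2-fold apart and RPL3 at −0.36 at 12 h, while from 3 h to 12 h the median was −0.07 (percentile 3.63), with no call. The 26 ribosome biogenesis genes had 0.01, −0.07 and −0.04, none high or low except at 6 h with means (low), with POLR1A, the largest subunit of RNA polymerase I, at −1.39 at 12 h. The 32 oxidative phosphorylation genes had 0.01, −0.03 and −0.07, none high or low, with NDUFC2 of complex I at −1.49 at 12 h. The 14 reference genes had 0.01, −0.07 and −0.12 and a mean of −0.02 at 3 h, none high or low, and TBP had 0.40 at 3 h. Medians within 0.02 of 0 changed sign under at least 1 of quantile normalization, centring and cyclic loess for the MAPK components and autophagy genes at 3 h and for the interferon, calcium and metallothionein lists at 6 h, as did EGFR at 6 h.

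Marker genes of cell types were followed beside these lists. The 15 epithelial and ovarian carcinoma markers had medians of −0.19, −0.18 and −0.11, low at 3 and 6 h, with 3 members at least 2-fold lower at each time and 0 higher, and both calls ended with the filter at the 75th percentile, the one at 6 h also with unmatched random lists, while the list was low at 12 h with means and with the filter at the median. Their median from 3 h to 12 h was −0.08 (percentile 28.5), with no call. CDH1, the epithelial cadherin, was at least 14.5-fold lower at each time and EPCAM, an epithelial adhesion molecule, had −1.72, −2.05 and −1.72. The 10 fibroblast markers had medians of 0.01, −0.02 and 0.04, none high or low, with a mean of −0.02 at 12 h. Their levels ranged widely: PDGFRA, named like FBLN1 and COL3A1 after its values were seen, lay below background on all 4 arrays, and COL1A2 had intensities of 40.5 at 0 h and 19.0 at 6 h, whereas COL1A1, a fibrillar collagen, had intensities of 11737 at 0 h and 6578 at 12 h, and LUM, a matrix proteoglycan, of 3763 and 6354. FBLN1, COL3A1, ACTA2, DCN and POSTN, of matrix and smooth muscle, had 11439, 7699, 9475, 3337 and 2182 at 0 h and 11819, 8821, 7177, 3398 and 4040 at 12 h. Of the leukocyte markers, the monocyte receptor CD14 had −1.71, −1.55 and −1.98 from an intensity of 238 at 0 h, FCER1G had −0.33, −0.04 and −0.56, and CD3E was at least 1.18-fold lower with all treated values below background. Of the endothelial markers, TEK had 0.38, 0.49 and −0.47, ESAM 0.23, 0.45 and 0.51, and PECAM1 lay below background at 0, 6 and 12 h.

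The array target of DDIT3 is the transcript NM_004083 on chromosome 12, from 57516588 to 57520517 in GRCh38.p14. HSPA5 (NM_005347) lies on chromosome 9 from 125234853 to 125241343, CHAC1 (NM_024111) on chromosome 15 from 40953471 to 40956512, CSF2 (NM_000758) on chromosome 5 from 132073789 to 132076170, and S100A9 (NM_002965) on chromosome 1 from 153357854 to 153361023.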

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

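The tests in this part were chosen after the results had been seen, except the one on the neighbours of ERBB2, which was set before its values were read. With 1 array per time, none of the differences between times was tested. ZFP36, which destabilizes AU-rich mRNAs, lay under its 0 h level at 3 h and over it at 12 h (log2 changes of −0.82 and 2.39). The ERK phosphatase DUSP6 went from −0.70 to 0.59 in the same way, and the tight-junction gene CLDN3 from −0.79 to 0.71. The median of the G1/S and DNA replication list stood at 0.19 and 0.11 at 3 and 6 h and at −0.17 at 12 h, on opposite sides of 0. Among the rows with no gene name, which entered no gene count, 1225 of 19791 over background were at least 2-fold higher at 12 h than at 0 h and 1016 at least 2-fold lower.

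Many squamous and epithelial genes were high on the 0 h array and low on the other 3: of 69 over background, 46 were at least 2-fold lower at each later time (43 with values below background set to background), 19 of these with all treated values below background, and 16 were within 2-fold throughout. A general stop of transcription with decay of short-lived mRNAs was argued against, since the short-lived immediate early transcripts had a median log2 change of 0.42 at 3 h. That median is measured against the same 0 h array, and the list also holds stress-induced genes, while its members EGR1 and FOS lay below their 0 h level. RNA of other, squamous-type cells on the 0 h array may account for the pattern: the 20 genes at least 2-fold lower at 12 h and still measurable at 3 h, a set without the genes lowest by 3 h, had medians of −2.21 from 0 to 3 h and of −0.28 from 3 to 12 h (quartiles −0.48 and −0.15), inside the central 95% of random lists of their level (−0.37 to 0.19). Against this as the whole cause, 18 of the 20 were lower at 12 h than at 3 h, which taking genes by their 12 h level favours, and 4 were within 2-fold at 3 h (CDS1, KRT15, LY6D and PKP1 at −0.92, −0.42, −0.22 and −0.01, followed by −0.10, −0.60, −1.07 and −1.03), while S100A2 and ITGB4 went on by −0.92 and −0.57. The keratins KRT14 and KRT17 had intensities of 11542 and 35574 at 0 h and were as high on the treated arrays, although a high level in the main cells would hide a small share of others. CDH1, EPCAM, CLDN3 and CLDN4 also belong to the ovarian carcinoma list, and the last pair did not stay low (0.71 and −0.11 at 12 h). A selective loss of these mRNAs in the same cells cannot be told apart from it, because no array lies between 0 and 3 h; it would need half-lives of at most 27.2 min for S100A9 and a median of 51.9 min over the 46 genes.

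Stress and inflammatory lists stood above 0 h, and a 0 h array that differs in its cells, with no further effect of exposure, could produce such differences. Their medians stood higher still at 12 h than at 3 h, which leaves that array out and argues against this as the whole cause: from 3 h to 12 h the NF-kB, ATF4 and CHOP, and ER chaperone medians stood at percentiles 100, 100 and 100 of random lists. For cholesterol genes (median −0.04, percentile 40.7), immediate early genes (0.06, 92.5), regulators that oppose death (0.21, 95.7), autophagy genes (0.08, 96.2), YAP/TAZ and TGF-beta targets (0.06, 91.8) and hypoxia genes (−0.03, 42.7), and for the lower heat shock (0.03, 85.2), G2/M (−0.03, 44.2), ribosomal protein (−0.07, 3.63) and ovarian carcinoma lists (−0.08, 28.5), the same comparison gave no call, so a share of their difference from 0 h stays open. An effect of elaiophylin on these genes remains a hypothesis, and an effect of fresh medium stays open and untested because each treated array had both.

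The ERBB2 target, on arrays of cells labelled SKOV3, a line known for amplified ERBB2, stood at percentiles 52.1, 47.9, 47.3 and 44.5 of named genes at 0, 3, 6 and 12 h. Intensities of different targets are not comparable as amounts of mRNA, and no reference profile of the line was used here, so these values do not show that ERBB2 was low. A weak ERBB2 target stays open: the 5 other genes of the amplicon had a median percentile of 40.8 at 3 h, under the bound of 90 set beforehand, but that bound assumed a level for amplified genes that no reference array in this design supplies, and the 5 genes, from 24.1 to 93.2, may also differ in their own expression. Cells other than the labelled line also stay open and cannot be told apart from it: CDKN2A, reported as deleted in this line, stood at percentile 99.8 at 3 h, and its neighbours CDKN2B and MTAP had intensities of 1270 and 1469 against a background of 33.3, but cross-hybridization of these targets was not tested, and the fibroblast markers COL1A1, FBLN1, ACTA2 and COL3A1 stood at 11543, 11382, 8642 and 8181, with no reference for their level in this line. No biological explanation was tested for this pattern.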

How the results depend on the processing

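The 3 h reference, the counts without squamous and epithelial genes, the filter on the brighter array and the background floor were chosen after seeing the data, whereas the other settings had been fixed earlier. No paired analysis was possible because each time had 1 array, and leaving out a replicate was not possible for the same reason. Of the 380 genes lower at 3 h, 310 were among the 3331 with the lowest mean level over all arrays. Of the 860 lower at 12 h, 458 were. A fall to background itself lowers that mean, so these numbers cannot show how far weak signal bears on the counts. With the brighter array at least 2 log2 units above background, 227 lower genes remained at 3 h and 636 at 12 h. Counts of genes 2-fold apart stayed within 1.5 times the main count, for each of the 5 steps and both directions, under quantile normalization, centring, cyclic loess, no filter and the brightest target. The normalizations could shift values only a little, since the deposited arrays already had nearly the same distribution. The 6 counts against 0 h without the squamous and epithelial lists also stayed within that bound. These lists could not have moved them past it, with 69 genes over background and 0 of them at least 2-fold higher. No named gene past 2-fold against 0 h changed sign under the 8 settings run for single genes, of which the filter at the 75th percentile kept 423 of 726 values. Most of these settings could not show such a change: the filters leave a gene's values as they are, and an added offset keeps the order of 2 values of 1 target. The 3 h reference was not among these 8, and against it CHAC1 at 12 h had −1.35 in place of 2.26, since its level was higher at 3 h than at 12 h.

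Counts below are given as higher and lower, in the order 3 h, 6 h and 12 h against 0 h, then 6 h against 3 h and 12 h against 6 h. With 1.5-fold as threshold they were 1065 and 864, 1192 and 1111, 1809 and 2100, 364 and 483, and 806 and 1085, and with 3-fold 47 and 212, 85 and 221, 222 and 318, 10 and 19, and 31 and 16, as a lower or higher threshold must give more or fewer genes. The filter at the 75th percentile of all values left 71 and 22, 94 and 28, 178 and 90, 7 and 4, and 21 and 7, since fewer genes were counted. With the filter at the median the counts outside 1.5 times were 129 lower at 3 h, 234 and 185 at 6 h, 466 lower at 12 h, 20 and 26, and 91 and 80, for the same reason. Adding 50 intensity units, which shrinks differences of dim genes, gave 145 and 212, 217 and 255, 526 lower at 12 h, 15 and 29, and 85 and 46. With the brighter array at least 2 log2 units over background, 227 were lower at 3 h and 293 at 6 h, followed by 29 and 35 and by 120 and 109, since fewer genes were counted. With values below background set to background, counts stayed within 1.5 times except for 36 and 53 at 6 h against 3 h, since differences below background no longer count. With the 3 h array as reference, 62 were higher and 122 lower at 6 h, and 343 and 476 at 12 h. This is another comparison and not another processing of the same one. It leaves out any difference from 0 h that was already there at 3 h.

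The line over hours called 0 rising and 0 falling genes in the main setting and also with log2(hours + 1), quantile normalization, centring, cyclic loess, no filter and the brightest target. It called 144 and 167 with the filter at the median, 88 and 80 with the filter at the 75th percentile and 86 and 71 with 50 units added, and the 3 treated arrays against the 0 h array gave 11 higher and 133 lower genes in limma; the cause of these differences was not tested. The fit of the 3 treated arrays against the 0 h array took different exposure times as replicates of 1 condition. Its residual is the spread between those times and holds no variation of the single 0 h array. Its counts are therefore no test of treatment over replicates. List medians kept their call in 79 of 93 cases with unmatched random lists and in 83 with means. They kept it in 90 or more under the 3 normalizations, and in 24 of 31 with the 3 h reference. Called medians had to keep their direction, but those with no call were counted as kept whatever their sign. An example is the p53 targets at 12 h, with a median of −0.04 and a mean of 0.19. The single reversal of a called median was that of cholesterol genes at 12 h, −0.040 with the 3 h reference against 0.40 with 0 h. The 3 h reference leaves out the difference already there at 3 h, when the median against 0 h was 0.33.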

Other observations

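The gene groups in this part were all chosen after the values were seen, and none of their differences was tested over replicates. Genes of the circadian clock and its outputs were higher: the 14 over background had medians of 0.56, 0.62 and 0.70 at 3, 6 and 12 h (percentiles 99.99, 99.99 and 99.98), with 3, 4 and 5 at least 2-fold higher and 0 lower, although from 3 h to 12 h the median of 0.13 was not high (percentile 90.3). NR1D2, a repressor of the clock, had log2 changes of 0.99, 1.58 and 2.30, PER2, a core component, had 1.67, 1.22 and 0.64, and the regulators BHLHE40 and NFIL3 had 1.23 and 1.15 at 12 h. DBP, an output factor, had −0.48, −0.80 and −0.91. Of the Krüppel-like factors, zinc-finger regulators of growth and differentiation, 17 were over background, with medians of 0.41, 0.48 and 0.85 (percentiles 99.95, 100 and 100) and of 0.45 from 3 h to 12 h (percentile 100), and at 12 h 6 were at least 2-fold higher and 2 lower. The lower pair, KLF1 and KLF8, lay below background at 12 h, and with such values set to background 0 were lower. KLF11 had 0.98, 1.33 and 1.89, KLF3 0.57, 0.88 and 1.74 and KLF2 −0.21, 0.78 and 1.59. The medians of both groups kept their direction under quantile normalization, centring and cyclic loess, which could change little because the deposited arrays already had nearly the same distribution.

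Ligands of the EGF receptor went apart. AREG, BTC and TGFA had log2 changes of −2.42, −2.04 and −0.85 at 3 h and of −2.10, −1.85 and −0.63 at 12 h, whereas EREG and HBEGF had 1.32 and 1.28 at 3 h and 3.05 and 1.75 at 12 h. From 3 h to 12 h AREG and TGFA had 0.32 and 0.22, so they were low only against the 0 h array, which stood apart in many squamous and epithelial markers. BTC had 0.19, but its log2 levels of 5.12, 4.92 and 5.31 at 3, 6 and 12 h lay near the background of 5.06, where a further fall cannot be read. The 383 genes with symbols of the form ZNF and a number, zinc-finger genes that are mostly of unknown function, had a median of 0.16 at 3 h (percentile 100), of −0.08 at 6 h (percentile 0.01) and of −0.11 at 12 h (percentile 8.78). From 3 h to 12 h their median was −0.26 (percentile 0), with 7 genes at least 2-fold higher and 32 lower (31 with values below background set to background). The 28 protocadherins, cell adhesion molecules known from neurons, had medians of −0.16, −0.27 and −0.72 (percentiles 5.98, 4.73 and 0) and of −0.62 from 3 h to 12 h (percentile 0.01). At 12 h 9 of them lay below background, and with such values set to background the medians were −0.12, −0.26 and −0.49, and −0.30 from 3 h to 12 h. The medians of both families kept their direction under the 3 normalizations, which could change little on such arrays. Changes also differed with the length of the gene on the genome: the 3331 genes with the shortest span, up to 10.96 kb, had medians of −0.06, −0.06 and −0.10, and the 3331 with the longest, from 71.1 kb on, of 0.11, 0.10 and 0.08. Between 3 h and 12 h these medians were −0.03 and −0.01.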
